A study of Mus musculus with 6 samples.

How the data were processed

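RNA was measured in 6 libraries of primary mouse muscle stem cells, 3 from control and 3 from Med23 knockout cells, after 3 days in culture. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads and strand-specific libraries were made with an NEBNext Ultra Directional kit. Per the submitters' processing notes, the authors used FastQC, cutadapt, STAR and Cuffdiff and the mm10 build. The versions, the annotation and whether Cuffdiff counted by strand are not given in the sources used here. Genes that overlap another gene, and genes with near-identical copies such as the actins and the ribosomal protein genes with their pseudogenes, are therefore uncertain to that extent.

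The authors deposited 1 table of 32973 genes with the FPKM of each library, as Cuffdiff scales them, and their own Cuffdiff comparison. The 2 group values of the authors' comparison were also FPKM. The control value equalled the mean of the control columns to within a relative difference of 3.33e-05, which was computed for the control group only. The authors' deposited p-values and q-values and their test statistic, a score, come from Cuffdiff, per the file headers, and were used only to set the authors' calls beside those made here. The deposited log2 fold changes were not used, since some of their cells held a spreadsheet error. The same spreadsheet step had turned 27 gene symbols into dates, 17 of them in tested rows, and these genes stay unnamed. Of 12368 genes listed by Ensembl identifier alone, 12316 matched the GENCODE vM21 annotation of mm10, from which coordinates were taken.

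FPKM are not counts, so no count model was used. The depth per library is unknown. Steps of 1 fragment in low genes did not give the relative depth, since at most 39.6% of the low genes of any pair of libraries shared 1 ratio (tolerance 0.03, log2). Precision is known only from the spread of the 3 libraries of a group. The sum of FPKM ranged from 697886 to 746973 in controls and from 599738 to 675095 in knockouts. Of these, the noncoding RNA gene Rmrp made up 225416 to 239590 in controls and 173041 to 205244 in knockouts, so both were lower in each knockout library. Without Rmrp the sums overlapped, at 468565 to 507383 and 426697 to 476046. Between 17259 and 17424 genes in controls and between 17681 and 17924 in knockouts were above 0. Such a 0 can also be a failed estimate, and 54 tested genes had a 0 in at least 1 library. The libraries' sex-linked genes were alike, with 4 Y-linked genes at 0 and Xist between 241 and 298 FPKM. All 6 library columns could be mapped to a sample by name.

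Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 12336. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, with genotype as the single factor, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Before the data were examined, 36 gene lists were fixed and tested with camera in limma, with a preset correlation of 0.01 and adjustment over the 33 lists that had at least 5 tested genes. Of the listed symbols, 5 had no row and 5 were found under an older name. Camera with an estimated correlation and fry were the alternatives for lists. Named genes followed a rule fixed in advance: Med23, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM (leaving out unnamed models), up to 4 members with the smallest adjusted p per described list, and 13 genes named whatever their values. Other called list members that are named, such as Myc, Klf2 and Junb, were chosen after their values were seen.

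The scripts were tested on simulated data made from the means and spreads of the knockout and control libraries over 12336 genes. Of the genes changed 1.5-fold, 2-fold and 4-fold, 32.8%, 67.2% and 95.5% were recovered. There were 140 calls, of which 10 were false, and 0 calls when no gene was changed. The changed genes were drawn from those with a mean of at least 5 FPKM on the log2(FPKM + 1) scale. Noise was drawn for each gene on its own, without the shifts that genes of a real library share. These shares may therefore not hold for low genes or for the real libraries. Alternatives covered the pseudocount, the filter on low values, quantile normalization and median scaling, the variance model, library weights, a fold threshold, a block for the replicate number, each library left out in turn and the authors' q-values.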

Results

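The series measured gene expression in primary mouse muscle stem cells, the Pax7-expressing cells that repair skeletal muscle. The cells were sorted by flow cytometry and cultured for 3 days on collagen in a growth medium with serum and basic fibroblast growth factor. Control cells carried loxP-flanked alleles of Med23 (3 libraries, Ctrl). Knockout cells carried the same alleles and a Pax7-driven, tamoxifen-inducible Cre recombinase (3 libraries, Med23KO). Med23 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Expression was given as FPKM (fragments scaled by transcript length and library size), and the number of reads per library is unknown. Each library had between 12017 and 12465 genes above 1 FPKM. Nothing in the labels says whether the libraries came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

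The comparison of both groups asks how the transcriptome of cultured muscle stem cells differs in Med23 knockout cells. Only the knockout cells carried the Cre recombinase, and no group carried it without the loxP-flanked alleles. Effects of Cre and of the loss of Med23 therefore cannot be told apart. The targeted gene was lower in each knockout library than in each control library. Med23 (ENSMUSG00000019984.16, mm10 chromosome 10, positions 24869986 to 24913681, plus strand) had 10.4, 11.7 and 10.2 FPKM in Ctrl replicates 1, 2 and 3. It had 5.10, 5.86 and 4.23 FPKM in Med23KO replicates 1, 2 and 3. The mean was 10.8 ± 0.783 FPKM (SD, n = 3) in controls and 5.06 ± 0.818 FPKM (SD, n = 3) in knockouts, 47.1% of the control level. The log2 fold change was -0.96 (SE 0.133, limma adjusted p = 0.0197), on the log2(FPKM + 1) scale used for every fold change here, which understates the change of low genes. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The value covers the whole gene, and the labels do not say which exons were removed. Transcript from the remaining exons, or from cells that kept the alleles whole, can be part of it, and the values do not separate these sources. With 1 library left out, the adjusted p ran from 0.00862 to 0.108, and it was above 0.05 in 5 of the 6 fits, those without Ctrl replicate 1, 2 or 3 or Med23KO replicate 1 or 2. The log2 fold change stayed between -1.06 and -0.86.

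Of the other Mediator subunits, 0 of 31 tested passed the test in either direction, with a median log2 fold change of -0.10 (camera adjusted p = 0.299). The lowest adjusted p in that list, 0.127, belonged to Med18, at 13.7 ± 0.584 FPKM in controls and 10.3 ± 1.31 FPKM in knockouts (SD, n = 3).

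Across the transcriptome, 184 genes were higher and 175 lower in the knockout among 12336 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 169 and 140 differed by more than 1.5-fold. The largest rises included the sarcomere genes Actc1 and Mybpc1 and the noggin gene Nog, and the largest falls the galanin gene Gal, the semaphorin gene Sema7a and the transcription factor gene Egr1. In all 359 genes the 3 knockout values lay on one side of the 3 control values, as they did in 24.7% of all tested genes, where chance gives 10%. The authors' deposited table called 2054 genes by Cuffdiff, 1130 higher and 924 lower, and 330 of the 359 were among them. Their shared direction is no separate check, since it was taken from the means of the same library columns. With the libraries scaled to equal medians, 351 genes were higher and 198 lower, so that 63.9% of the calls were rises. The counts depended on single libraries: they were 754 higher and 400 lower without Med23KO replicate 3, 3 and 10 without Med23KO replicate 2, and 16 and 39 without Med23KO replicate 1, and 47 and 44, 6 and 17, and 26 and 45 without Ctrl replicates 1, 2 and 3.

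**Figure D1:**
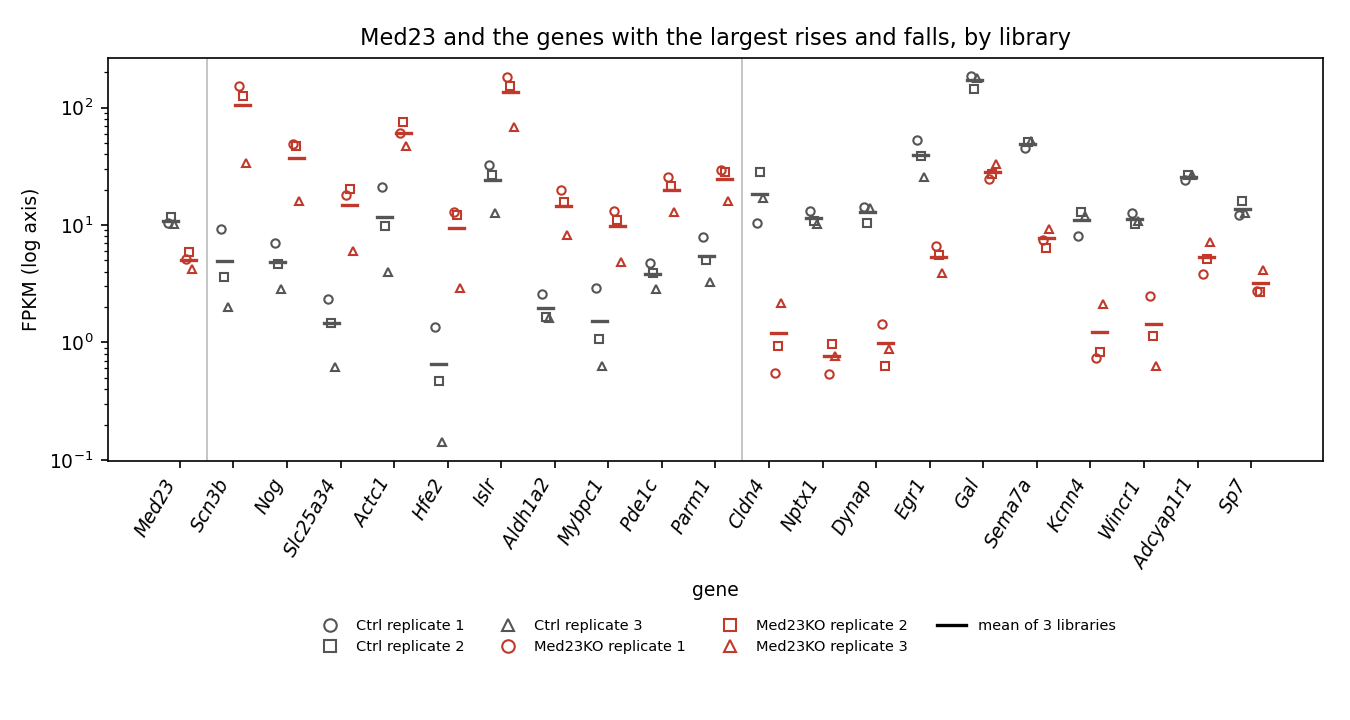
FPKM of Med23 and of the 10 genes with the largest rises and the 10 with the largest falls, on a log axis, for each library (symbols, 3 per group) with the mean of each group (bars). In each gene shown the 3 knockout values lie on one side of the 3 control values, and in each of the 10 rises Med23KO replicate 3 is the lowest of the 3 knockout libraries.

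The largest rise was in Scn3b, a beta subunit of voltage-gated sodium channels (ENSMUSG00000049281.16, mm10 chromosome 9, positions 40269217 to 40291618, plus strand). It had 4.96 ± 3.81 FPKM in controls and 104 ± 62.6 FPKM in knockouts (SD, n = 3), a log2 fold change of 4.08 (SE 0.626, limma adjusted p = 0.0234). Nog, which encodes the secreted bone morphogenetic protein antagonist noggin, rose from 4.89 ± 2.11 to 37.3 ± 18.6 FPKM (SD, n = 3; log2 fold change 2.61). The cardiac alpha-actin gene Actc1, expressed in developing muscle, rose from 11.6 ± 8.70 to 61.2 ± 14.6 FPKM (log2 fold change 2.53). Islr rose from 24.0 ± 10.2 to 134 ± 58.7 FPKM, and Aldh1a2, which makes retinoic acid, from 1.95 ± 0.548 to 14.6 ± 5.82 FPKM. The mitochondrial carrier gene Slc25a34, the hemojuvelin gene Hfe2, the slow-type myosin-binding protein gene Mybpc1, the phosphodiesterase gene Pde1c and Parm1 made up the rest of the 10 largest rises, with log2 fold changes between 2.02 and 2.58. Each of these 10 calls was lost when Med23KO replicate 2 was left out, with adjusted p-values up to 0.207 over the fits without 1 library.

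The largest fall was in Cldn4, a tight junction gene, from 18.5 ± 8.97 to 1.21 ± 0.835 FPKM (SD, n = 3; log2 fold change -3.10, SE 0.375, limma adjusted p = 0.0137). The galanin gene Gal (ENSMUSG00000024907.7, mm10 chromosome 19, positions 3409915 to 3414544, minus strand) fell from 170.3 ± 22.0 to 28.3 ± 4.41 FPKM (log2 fold change -2.55, SE 0.144, adjusted p = 0.000909). The semaphorin gene Sema7a fell from 49.2 ± 3.60 to 7.73 ± 1.47 FPKM (log2 fold change -2.53), and the neuronal pentraxin gene Nptx1 from 11.4 ± 1.48 to 0.759 ± 0.216 FPKM (log2 fold change -2.81). Dynap fell from 12.8 ± 2.09 to 0.987 ± 0.419 FPKM. The growth-factor-induced transcription factor gene Egr1 fell from 39.3 ± 13.7 to 5.38 ± 1.38 FPKM (log2 fold change -2.62, SE 0.270). The potassium channel gene Kcnn4, the long noncoding RNA gene Wincr1, the neuropeptide receptor gene Adcyap1r1 and the osteoblast transcription factor gene Sp7 completed the 10 largest falls, with log2 fold changes between -2.45 and -1.81. Nptx1, Dynap, Gal and Sema7a stayed past the threshold without any 1 of the 6 libraries, which was true of 11 of the 359 called genes.

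Regulators of the muscle stem cell state gave a mixed picture. Pax7, the marker of the stem cells, had 46.2 ± 11.6 FPKM in controls and 48.6 ± 14.4 FPKM in knockouts (log2 fold change 0.05, SE 0.261). Myf5 had 78.4 ± 14.3 and 92.8 ± 29.1 FPKM, and Myod1, a determination factor of the muscle lineage, 948 ± 235 and 786 ± 213 FPKM (SD, n = 3 each). Neither passed the main test, with limma adjusted p-values of 0.711 and 0.607. Over the limma refits that kept all 6 libraries, the lowest adjusted p was 0.173 for Myf5 and 0.0194 for Myod1, past the threshold. Myog, the myogenin gene that marks entry into differentiation, had 30.2 ± 14.7 and 83.3 ± 6.82 FPKM, with a log2 fold change of 1.56 (SE 0.343) that missed the threshold (adjusted p = 0.0609). It was past the threshold without Med23KO replicate 3 (adjusted p = 0.0371), without Ctrl replicate 3 (adjusted p = 0.0485), under quantile normalization (adjusted p = 0.0434), median scaling (adjusted p = 0.039) and library weights (adjusted p = 0.0212), and in the authors' deposited table (q = 0.000695), with a highest adjusted p of 0.236 over all settings. Bcl6, Egr2, Fos, Srf, Elk1 and Pparg had log2 fold changes of -0.18, -0.37, 0.03, -0.33, -0.08 and 0.23, and 0 of these 6 passed the main test. Of these, Srf alone went past the threshold in a limma refit that kept all 6 libraries (lowest adjusted p = 0.0143).

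Genes of myogenic differentiation rose as a list. Of 36 tested, 10 rose and 0 fell over all genes tested, and 25 were higher and 1 lower when adjusted over the list alone. The median log2 fold change was 1.01 (camera adjusted p = 2.98e-13, and adjusted p = 0.59 with an estimated correlation). The troponin C gene Tnnc1 rose from 13.3 ± 2.55 to 30.1 ± 3.25 FPKM, and the myosin light chain gene Myl4 from 5.04 ± 2.05 to 21.5 ± 4.4 FPKM (SD, n = 3). The transcription factor gene Mef2c rose from 1.12 ± 0.227 to 3.93 ± 0.821 FPKM, and the Z-disc gene Actn2 from 0.804 ± 0.483 to 6.10 ± 2.09 FPKM. Relative to the control mean, the list median was 0.34, 0.01 and -0.27 (log2) in Ctrl replicates 1, 2 and 3, and 1.00, 1.08 and 0.68 in Med23KO replicates 1, 2 and 3.

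Genes of ribosome biogenesis fell as a list, and their members moved closely together. All 28 tested members had a negative log2 fold change, with a median of -0.49 and an SD of 0.114. Of these, 8 fell over all genes tested and 24 adjusted over the list alone (camera adjusted p = 1.32e-15, and adjusted p = 0.194 with an estimated correlation). The fibrillarin gene Fbl fell from 111 ± 4.63 to 77.0 ± 1.99 FPKM, and Nhp2 from 77.1 ± 3.31 to 51.0 ± 1.24 FPKM (SD, n = 3). Gar1, like Nhp2 a part of the box H/ACA particles that modify ribosomal RNA, fell from 25.7 ± 2.84 to 14.8 ± 0.546 FPKM. Mybbp1a fell from 119 ± 4.31 to 83.5 ± 1.92 FPKM. The genes of the cytosolic ribosomal proteins had a smaller median of -0.12, with 0 of 44 past the test over all genes and 0 over the list alone. The ribosomal protein list was called lower (camera adjusted p = 0.0055, and adjusted p = 0.901 with an estimated correlation), but under quantile normalization its median was 0.02 and its adjusted p 0.336. It was also not called without Ctrl replicate 1 (median -0.07, adjusted p = 0.22), without Med23KO replicate 3 (adjusted p = 0.0559) or with library weights (median -0.07, adjusted p = 0.232).

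Genes of the G1/S transition and DNA replication were called lower as a list, with small differences. Their median log2 fold change was -0.18, and 37 of 40 lay below 0. None of the 40 passed over all genes tested, and 7 were lower adjusted over the list alone (camera adjusted p = 8.55e-06, and adjusted p = 0.194 with an estimated correlation). The replication helicase gene Mcm6 had 80.8 ± 4.09 FPKM in controls and 61.4 ± 3.22 FPKM in knockouts, and Mcm7 had 92.7 ± 4.55 and 72.0 ± 1.5 FPKM (SD, n = 3). The 40 G2/M genes had a median of -0.12, 0 passed, and the list was not called (camera adjusted p = 0.052). It was called lower without a filter on low values (adjusted p = 0.0034) and without Ctrl replicate 1 (adjusted p = 0.0131), Ctrl replicate 2 (adjusted p = 0.0298) or Med23KO replicate 3 (adjusted p = 0.00488), while without Ctrl replicate 3 its median was -0.07 (adjusted p = 0.425). The proliferation marker Mki67 had 86.3 ± 8.91 FPKM in controls and 86.1 ± 2.45 FPKM in knockouts (log2 fold change 0.00, SE 0.0996).

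Immediate-early genes, which growth factors induce within minutes, were called lower as a list, but the change was uneven. Of 26 tested, 6 fell and 1 rose over all genes, and 10 were lower and 2 higher adjusted over the list alone. The median log2 fold change was -0.20 (camera adjusted p = 0.00639, and adjusted p = 0.857 with an estimated correlation). Relative to the control mean, the list median was 0.09, 0.10 and -0.20 (log2) in Ctrl replicates 1, 2 and 3, and -0.18, -0.22 and -0.44 in Med23KO replicates 1, 2 and 3, so that Med23KO replicate 1 lay within the control range. Beside Egr1, the falls were in Egr3 (11.8 ± 1.70 to 3.58 ± 0.627 FPKM), Dusp5, a phosphatase gene induced by ERK (19.7 ± 3.07 to 6.33 ± 0.456 FPKM), Klf2, Myc and Junb. Myc fell from 38.8 ± 5.91 to 20.4 ± 3.70 FPKM (SD, n = 3; log2 fold change -0.90). The antiproliferative gene Btg2 rose from 12.0 ± 1.01 to 21.4 ± 1.73 FPKM. The list was not called without Med23KO replicate 3 (adjusted p = 0.0578) or among genes with a mean of at least 5 FPKM (adjusted p = 0.0616). The ERK and FGF feedback genes had a median of 0.16, with Etv1 higher and Dusp5 lower among 16 tested, and were not called (camera adjusted p = 0.393), but without Med23KO replicate 3 their median was 0.38 and the list was called higher (adjusted p = 0.0211).

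**Figure D2:**
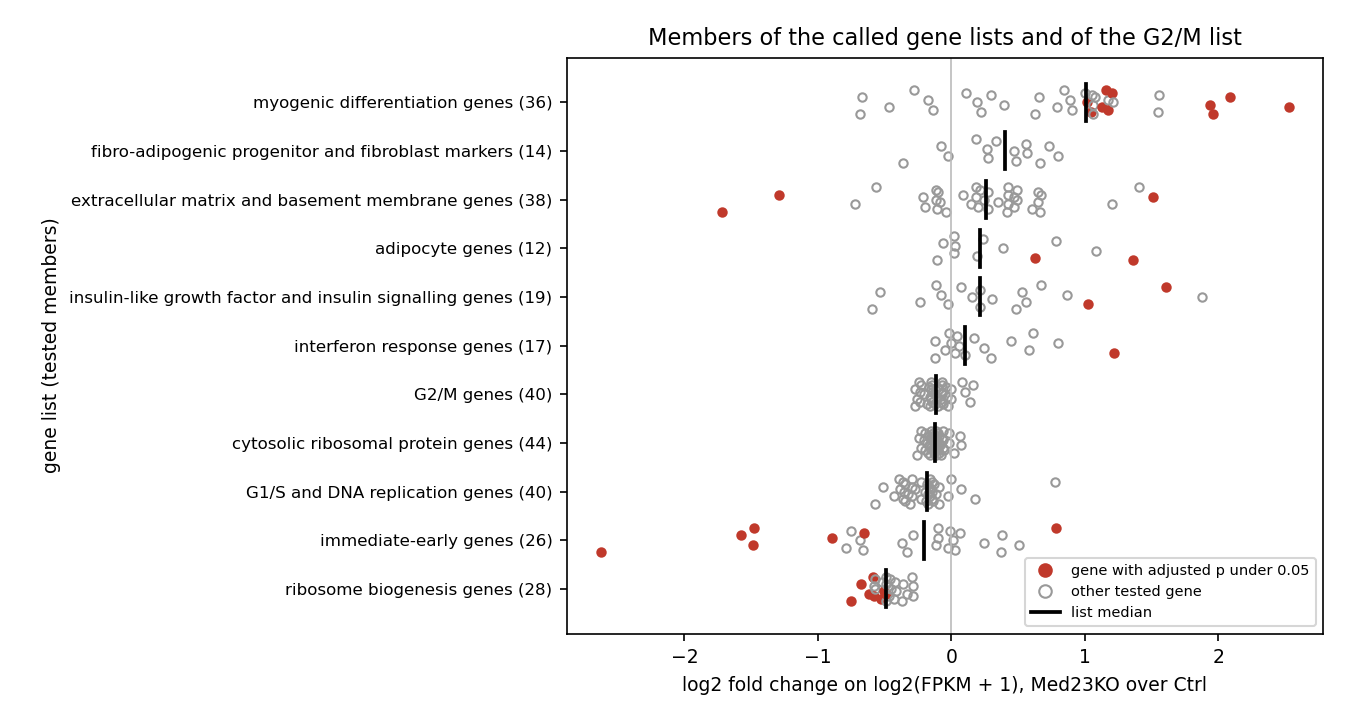
Log2 fold change on log2(FPKM + 1), knockout over control, of each tested member (points) of the 10 called gene lists and of the G2/M list, with the list median (black bars) and genes past adjusted p 0.05 filled in red. All 28 ribosome biogenesis genes lie below 0, and the median of the 36 myogenic differentiation genes lies at 1.01.

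Markers of fibro-adipogenic progenitors and fibroblasts, cells that a sort of muscle stem cells can also hold, moved in the same direction as the myogenic differentiation, extracellular matrix, insulin-like growth factor and adipocyte genes. Their median log2 fold change was 0.40, with 11 of 14 above 0 (camera adjusted p = 0.0055, and adjusted p = 0.751 with an estimated correlation). None of the 14 passed the test, over all genes or adjusted over the list alone. Dcn had 6.14 ± 1.02 FPKM in controls and 9.47 ± 0.850 FPKM in knockouts, and Col3a1 had 161 ± 21.9 and 242 ± 52.5 FPKM (SD, n = 3). Relative to the control mean, the median of the markers was 0.63, 0.24 and 0.22 (log2) in Med23KO replicates 1, 2 and 3.

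Among extracellular matrix and basement membrane genes, 1 of 38 rose and 2 fell, and 3 were higher and 3 lower adjusted over the list alone. The list was called higher, with a median of 0.26 (camera adjusted p = 0.00742, and adjusted p = 0.751 with an estimated correlation). Col12a1, a fibril-associated collagen gene, rose from 7.17 ± 0.974 to 22.2 ± 1.83 FPKM (SD, n = 3). Against the direction of the list, the tenascin C gene Tnc fell from 184 ± 32.2 to 55.9 ± 16.2 FPKM, and Col18a1 from 81.9 ± 14.8 to 32.7 ± 2.46 FPKM. Relative to the control mean, the list median was 0.03, 0.08 and -0.13 (log2) in Ctrl replicates 1, 2 and 3, and 0.41, 0.30 and 0.03 in Med23KO replicates 1, 2 and 3, so that Med23KO replicate 3 lay within the control range. Without Med23KO replicate 1 the list median was 0.12 and the list was not called (adjusted p = 0.0821).

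Of the insulin-like growth factor and insulin signalling genes, 2 of 19 rose, 6 were higher adjusted over the list alone, and the median was 0.21 (camera adjusted p = 0.0055, and adjusted p = 0.751 with an estimated correlation). Relative to the control mean, the list median was 0.11, 0.11 and -0.19 (log2) in Ctrl replicates 1, 2 and 3, and 0.53, 0.28 and -0.08 in Med23KO replicates 1, 2 and 3, so that Med23KO replicate 3 lay within the control range. The list median was 0.06 without Med23KO replicate 1, 0.09 without Ctrl replicate 3 and 0.42 without Med23KO replicate 3. The growth factor gene Igf1 rose from 0.578 ± 0.172 to 3.85 ± 0.940 FPKM, and Igfbp7, a binding protein gene, from 85.3 ± 20.4 to 172 ± 20.9 FPKM (SD, n = 3). Igf2 had 89.0 ± 33.4 and 341 ± 155 FPKM and missed the threshold (limma adjusted p = 0.0652). Of 12 adipocyte genes, 2 rose and 3 were higher adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.00811, and adjusted p = 0.751 with an estimated correlation). The lipid droplet gene Plin2 rose from 78.0 ± 4.10 to 121 ± 2.14 FPKM, and the lipoprotein lipase gene Lpl from 10.7 ± 3.14 to 28.9 ± 8.10 FPKM. The adipocyte median was 0.60, 0.23 and -0.01 in Med23KO replicates 1, 2 and 3, against 0.21, -0.02 and -0.20 in the control replicates. It was 0.08 without Med23KO replicate 1 and 0.43 without Med23KO replicate 3, and the list was not called without Ctrl replicate 3 (adjusted p = 0.0548). Of 17 interferon response genes, Ifit1 alone rose, over all genes and adjusted over the list alone, from 0.402 ± 0.142 to 2.29 ± 0.586 FPKM. The interferon list had a median of 0.10 (camera adjusted p = 0.022, and adjusted p = 0.859 with an estimated correlation). Its median was 0.19, 0.25 and 0.02 in Med23KO replicates 1, 2 and 3, against 0.16, -0.04 and -0.09 in the control replicates, and 0.24 and 0.21 without Ctrl replicate 1 and Med23KO replicate 3. It was not called without Ctrl replicate 2 (median 0.07, adjusted p = 0.086), without Ctrl replicate 3 (median 0.01, adjusted p = 0.112), without Med23KO replicate 2 (median 0.02, adjusted p = 0.108), under quantile normalization (adjusted p = 0.142) or among genes with a mean of at least 5 FPKM (adjusted p = 0.451).

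In all, 6 of 33 tested lists were called higher and 4 lower, and 0 were called with an estimated correlation, where 2 lists had an unadjusted p under 0.05. The muscle stem cell quiescence list was not called (camera adjusted p = 0.0547), although 2 of its 31 tested members rose, Btg2 and the cell cycle inhibitor gene Cdkn1c (1.76 ± 0.703 to 6.38 ± 1.11 FPKM; SD, n = 3). The quiescence list was called higher under quantile normalization (adjusted p = 0.0349), with library weights (adjusted p = 0.0136) and without Ctrl replicate 1 (adjusted p = 0.00731), Ctrl replicate 2 (adjusted p = 0.0472) or Med23KO replicate 3 (adjusted p = 0.00115), while without Med23KO replicate 1 its adjusted p was 0.637. The smooth muscle and MRTF-SRF target list was not called either (camera adjusted p = 0.988), although the smooth muscle actin gene Acta2 rose from 145 ± 13.4 to 267 ± 21.5 FPKM and Cnn3 also rose, among 23 tested. Endothelial, leukocyte and pericyte markers were not called as lists, with camera adjusted p-values of 0.908, 0.927 and 0.33 over 7, 6 and 6 tested genes, and Acta2, which is also among the pericyte markers, was the only member that passed. The lists of Schwann, tenocyte and erythroid markers had 4, 4 and 0 tested genes, fewer than the 5 required. Single called genes in lists that were not called included the serine synthesis gene Phgdh, which fell from 71.6 ± 3.21 to 32.7 ± 0.669 FPKM, the transketolase gene Tkt, which fell from 18.5 ± 1.13 to 9.21 ± 1.24 FPKM, and the muscle enolase gene Eno3, which fell from 283 ± 11.8 to 175 ± 16.8 FPKM (SD, n = 3). The plasminogen activator gene Plau fell from 63.4 ± 3.52 to 29.3 ± 5.12 FPKM, and Notch2 from 33.5 ± 2.33 to 23.4 ± 0.456 FPKM.

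Med23KO replicate 3 stood apart from the other knockout libraries. On the first principal component, which held 50.8% of the variance, it scored -6.17, against 32.3 and 24.5 for Med23KO replicates 1 and 2 and -3.31, -17.6 and -29.7 for Ctrl replicates 1, 2 and 3. On the second component, with 26.1%, it scored -27.4, below the control range of -4.53 to 23.6. Its Med23 value of 4.23 FPKM was the lowest of the 6 libraries. Ctrl replicate 3 likewise scored lowest of the controls on both components, at -29.7 and -4.53. A shift shared by both libraries numbered 3 therefore cannot be told from a trait of Med23KO replicate 3 alone. Pearson's r across genes, which are not independent replicates, ranged from 0.965 to 0.987 within groups and from 0.948 to 0.979 between them.

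**Figure D3:**
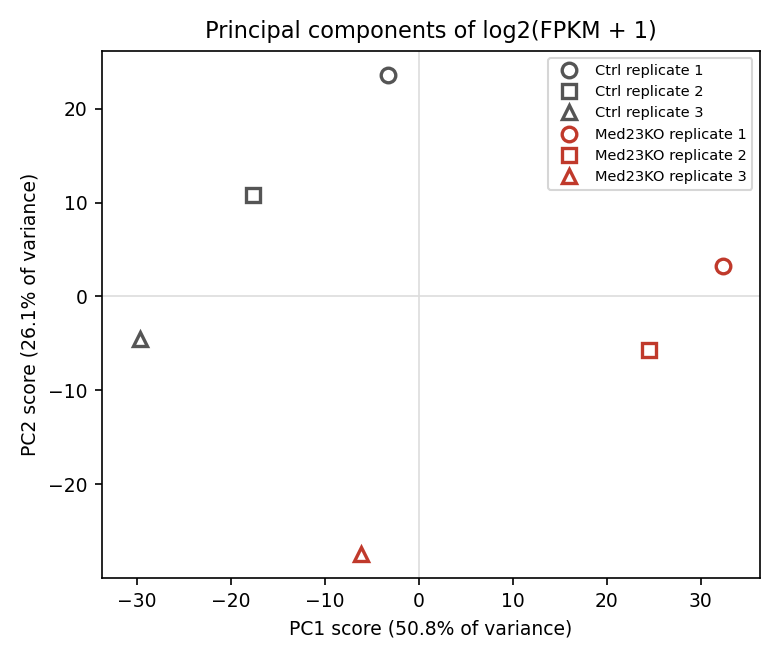
Scores of the 6 libraries on the first (x axis, 50.8% of the variance) and second (y axis, 26.1%) principal components of log2(FPKM + 1) over 12336 genes, with colour for the group and symbol for the replicate number. Med23KO replicates 1 and 2 lie to the right at 32.3 and 24.5, and Med23KO replicate 3 lies at -6.17 on the first component, within the control range, and at -27.4 on the second, below the control range of -4.53 to 23.6.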

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

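All alternatives were chosen before the data were examined. None of the 359 called genes changed sign in any of the refits with limma. Since the 2 groups did not overlap in any of these genes, only quantile normalization and median scaling could have changed a sign. The counts of called genes moved. The main test gave 184 genes higher and 175 lower. Without a filter they were 73 and 84, with library weights 850 and 850, and by the authors' q-values 1130 and 924. Quantile normalization and median scaling gave 298 and 351 genes higher. With 1 library left out they ranged from 3 to 754 higher and from 10 to 400 lower, the lowest without Med23KO replicate 2 and the highest without Med23KO replicate 3, and 11 of the 359 genes were called in every such fit. The log2 fold change of Med23 ranged from -1.06 to -0.86 over those fits. Its call was lost in 5 of them, all but that without Med23KO replicate 3 (limma adjusted p = 0.00862). All of these fits have fewer residual degrees of freedom than the main fit, so that alone does not account for which of them lost the call. The adjusted p of Med23 was between 0.0019 and 0.0447 in the other refits, and its q-value in the authors' table was 0.000695. The 6 lists higher and 4 lower became 0 and 0 with an estimated correlation and 0 and 2 with fry. The 2 lists that fry called lower were ribosome biogenesis (fry adjusted p = 0.00906) and G1/S and DNA replication (fry adjusted p = 0.00754). The myogenic differentiation list was not called by fry (adjusted p = 0.0942). With 1 library left out the called lists ranged from 4 to 9 higher and from 3 to 5 lower. The cytosolic ribosomal protein list reversed under quantile normalization, with a median of 0.0172 and an adjusted p of 0.336 (range over its alternatives 0.000254 to 0.901). The cause of these moves was not tested unless stated. Over single genes and alternatives, 1241 results kept their side of the threshold, 223 lost it, 72 gained it and 0 reversed, with 9 further sign changes among genes called in neither setting. Over lists the numbers were 545, 30, 16 and 1. The replicate number as a block gave 1180 genes higher and 1577 lower and called Myog (adjusted p = 0.00705), the G2/M list lower (adjusted p = 0.01) and the quiescence list higher (adjusted p = 0.0109). Same-numbered libraries deviated together with correlations of 0.437, -0.0158 and 0.563, and 4 of 6 libraries correlated best with their own number. As a further hint from the data, 39.6%, 30.1% and 20.8% of low genes shared 1 ratio in the same-numbered pairs, against at most 13.8% in all other pairs. The labels give no pairing. The library weights stopped short of their tolerance and gave Ctrl replicate 2 a weight of 7.76. Lists have no value under the authors' q-values or the fold threshold, and the alternative for counts was not run, since the values are FPKM. The unknown depth sets no separate limit that could be tested.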

Other observations

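The lists, single genes and tests of explanations in this part were chosen after the values were seen, except the counts over other splits and the tests of unconfirmed gene models. Genes of serine, one-carbon and purine synthesis were mostly lower. Of 31 tested, 10 fell and 0 rose over all genes, 28 lay below 0, and the median log2 fold change was -0.42. Both lists of this part were put together with their values in view, so no test of them as lists is given. The folate carrier gene Slc19a1 fell from 15.2 ± 1.98 to 7.98 ± 0.281 FPKM, Mtap, of methionine salvage, from 77.5 ± 11.4 to 43.4 ± 5.89 FPKM, and the purine synthesis gene Pfas from 33.3 ± 2.71 to 22.6 ± 0.947 FPKM (SD, n = 3). Of 35 imprinted genes, 30 lay above 0, with a median of 0.23, and Cdkn1c alone passed the test. Peg3 had 224 ± 24.5 FPKM in controls and 365 ± 72.2 FPKM in knockouts, and Meg3 had 5.95 ± 1.94 and 15 ± 4.46 FPKM, and neither passed (limma adjusted p = 0.0658 and 0.0652).

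Beside Nptx1, Dynap, Gal, Sema7a, Phgdh and Col12a1, the genes called in every fit without 1 library were Errfi1, Hmga2, Gcnt4, Ptgr1 and Palmd. Errfi1, which encodes a feedback inhibitor of EGF receptors, fell from 364 ± 21.1 to 124 ± 11.6 FPKM, and Hmga2, a chromatin protein gene of growing progenitors, from 161 ± 13.2 to 66.8 ± 4.12 FPKM (SD, n = 3). Palmd rose from 2.40 ± 0.0729 to 9.67 ± 1.66 FPKM. Their limma adjusted p-values were 0.002, 0.00356 and 0.00592.

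The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 184 genes higher and 175 lower, and the most genes that any other split called in 1 direction was 10, so for each count 1 split, the real one, reached it. For lists, 5 of the 10 splits reached the 6 called higher in 1 direction and 7 the 4 called lower, with 11 as the highest of the other splits.

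Ribosome biogenesis genes were lower with little spread between members. A smaller share of cycling cells is argued against as the whole cause, since the median of the G2/M genes lay 0.371 above that of the ribosome biogenesis genes. That is more than the SDs of both lists together (0.106 and 0.114), which measure the spread between genes. The rule was set with both medians in view. A part stays open, since 34 of 40 G2/M genes and 37 of 40 G1/S and DNA replication genes also lay below 0. Unequal scaling of the libraries is argued against too: the ribosome biogenesis median was -0.437 under quantile normalization and -0.46 under median scaling. The camera adjusted p-values were 4.57e-13 and 1.82e-13 at the preset correlation. Camera compares the members with the other genes, so a shift common to a library could hardly end the list's call, and only the medians bear on scaling. With an estimated correlation the list was not called in the main fit (adjusted p = 0.194). An effect of the knockout may account for it as a hypothesis, and Myc, a driver of ribosome synthesis, was also lower, but whether one depends on the other was not tested.

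Egr1, Egr3, Dusp5 and Klf2 were lower, with log2 fold changes of -2.62 to -1.48 and a median of -1.53. They were the 4 lowest of the tested immediate-early genes, so their distance from the median of another set carries no weight. Lower activity of the ERK pathway as a whole, reaching its targets alike, is argued against as the whole cause. The 16 tested ERK and FGF feedback genes had a median of 0.156 (SD 0.602), with 12 above 0. Dusp5, which belongs to both sets, Fosl1 (-0.75) and Ccnd1 (-0.57) were among the 4 below 0. Lower ERK activity that reached only some targets therefore stays open. The list was not called (camera adjusted p = 0.393, and adjusted p = 0.997 with an estimated correlation), except higher without Med23KO replicate 3 at the preset correlation (median 0.377, adjusted p = 0.0211). Handling before lysis stays open. The median of 9 rapidly induced genes (Fos, Fosb, Jun, Junb, Ier2, Ier3, Nr4a1, Dusp1 and Zfp36) was -0.114 (SD 0.436), with Ier2, Fosb, Jun and Junb among the 5 below 0, and the set leaves out other called immediate-early genes, such as Myc. Both sets were held to the same rule, a median at or above 0, and rules were changed after the values were seen: by another that asked only for a distance from the 4 genes of more than the SD, handling would be argued against as the whole cause too. A selective effect of the knockout on Egr-family and related genes may be the source, as a hypothesis, and handling and genotype cannot be told apart here, since some rapidly induced genes were lower along with them and others were not.

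Unconfirmed gene models, single-exon models that the annotation lists as still to be tested, were higher more often than lower: of 743 tested, 23 were called higher and 3 lower, with a median log2 fold change of 0.07. Of these models 62.7% lay above 0, and of 10609 protein-coding genes 43.3%. Genes of long intergenic noncoding RNA and of antisense RNA leaned the same way, with 60.6% of 180 and 57.3% of 124 above 0. Med23KO replicate 2 carried most of the shift of the unconfirmed models: relative to the control mean, their median was 0.171 there, 0.047 and 0.0439 in Med23KO replicates 1 and 3, and between -0.0295 and 0.0179 in controls. More unspliced RNA or genomic DNA in the knockout libraries stays open: the 267 models inside a protein-coding gene of the same strand that was not itself higher had a median of -0.0476 (95% bootstrap interval -0.0813 to -0.01), but choosing them by their host gene also chooses models that did not rise, and the level of 0.3 set in advance lay above the whole shift. Over 615 models with 1 such host gene, the log2 fold changes of model and host had a Spearman's rho of 0.632 across genes, which are not independent (permutation p = 1e-04, the smallest that 10000 permutations can give). The models may therefore follow the transcription of their host genes, or take up reads of unannotated parts of them, and these options were not separated.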
